A study of Sus scrofa with 10 samples.

How the data were processed

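RNA from pig liver (Sus scrofa) was measured by RNA sequencing in 10 libraries of a study of liver failure after hepatectomy and of a bioartificial liver, a device outside the body through which blood is passed over liver cells. The labels place 3 libraries in normal liver on day 0 (Control), 2 in liver failure without a device on day 2 (NoBAL), 2 in liver failure with a device that held no cells on day 3 (EmptyBAL), 1 on day 4 of a device filled with human induced hepatocytes (hiHepD4) and 2 on day 8 of that device (hiHepD8). Human induced hepatocytes are hepatocyte-like cells made by direct conversion of another human cell type. Per the labels' protocols, total RNA was taken from the livers with Trizol and sequenced as paired-end TruSeq libraries on an Illumina HiSeq instrument. The labels give the cell type as hepatocyte but the source as liver and name no cell isolation step, so the values were treated as those of liver tissue.

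The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to the fragments sequenced), with 31905 genes and 10 libraries. The submitters' processing notes name HISAT2, Cufflinks and HTSeq and the builds Sscrofa11.1 and mm10, without saying which step each served. Since the table carries pig gene identifiers, mm10, a mouse build, was not used here. FPKM are scaled to the fragments of each library, so a rise of a few abundant genes lowers all others. The deposited FPKM summed to between 439925 and 829970 per library, and 10366 to 10862 genes reached 1 FPKM. Among low values, a single ratio between Control replicates 1 and 3 held for 73 of 2430 genes, and between the hiHepD8 replicates for 74 of 2846, too few to recover whole fragments. The depth of the libraries is therefore unknown and no counting intervals are given. Whether the library kit kept strand information is not given in the sources used here, so overlapping and antisense genes and near-identical paralogs, among them cytochrome P450 and U3 small nucleolar RNA genes, are uncertain.

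Gene symbols came from the deposited table for 16497 genes and from a reference table matched on the gene identifier for 851 more, and 14557 genes had none. Of the 644 genes in the fixed lists, 578 were found by symbol. For 1273 genes a more abundant gene had the same symbol, and the list tests used the more abundant one. Coordinates of named genes are those of Sscrofa11.1, matched by symbol; among the genes the text names, CYC1, CYP2D6, HSD17B6, NRIP3, TF and U3 had no match.

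Values were tested as log2(FPKM + 1), with a pseudocount of 1, which understates the change of genes with low FPKM; every log2 change given is on this scale. Genes with at least 1 FPKM in at least 2 libraries entered, 12180 in all. All 10 libraries were fitted in 1 limma model (version 3.58.1 in R 4.3.3; moderated statistics with a mean-variance trend) with a mean for each of the 5 groups, which left 5 residual degrees of freedom and a prior of 2.7. The test was two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. hiHepD4, a single library, was not tested; its lists were placed among 10000 random lists of the same size matched on mean expression. Standard errors of log2 changes are limma's, and SDs are of FPKM. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

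Of 33 gene lists fixed in advance, for liver functions, stress responses, proliferation and cell types, 31 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Each test was run again with a correlation estimated from the data. That rerun differed in more than the correlation: for bile acid synthesis in NoBAL against Control the estimate was 0.002, below the preset 0.01. Its adjusted p still went from 5.3e-05 to 0.071. A call lost in the rerun is therefore not by itself a sign of correlated genes. Beside camera, fry was computed, which asks whether the members change at all rather than more than other genes. Lists of red cell and platelet genes had 3 and 4 measured members and were not tested. The rule for named genes took, for NoBAL against Control and hiHepD8 against NoBAL, the 10 genes with the largest rise and the 10 with the largest fall among those called whose libraries did not overlap between groups, with a symbol and a mean of at least 10 FPKM in the higher group. The other comparisons took 5 and 5 by the same rule. From each list up to 4 called members with the largest change were named, or, where none was called, up to 2 with the highest mean. The groups, the tests, the lists, this rule and the other settings listed last were chosen before the data were examined.

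The labels do not say whether libraries of 1 group came from separate animals, so p-values measure only the spread between libraries, which may be technical. The Control libraries, and likewise the hiHepD8 libraries, were nearly identical. Up to 100 FPKM, their spread was 1.0 to 1.3 times the counting error scaled from the genes at 1 to 2 FPKM. At 1000 FPKM or more it was 3.1 times that error for Control replicates 1 and 3 and 4.6 times for hiHepD8. Separate handling of the same RNA could give such an excess, so it does not show that the libraries came from separate animals. They were kept apart in the main fit only because this was the design chosen beforehand. After the data had been seen, every result was also computed with Control replicates 1 and 3 averaged and the hiHepD8 pair averaged (pairs averaged), and with each of these groups entered as 1 value (groups counted once, which leaves 2 residual degrees of freedom).

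The fit was tested on simulated data for NoBAL against Control with 12180 genes, 200 of them changed, in 10 simulations. With independent libraries it recovered 97.6% of the genes changed by 3 on the log2 scale and 77.6% of those changed by 1.5, with 10.7 false calls on average. Where a single animal stood behind each near-identical group, it recovered 98.8% and 86.4% but made 1849.2 false calls on average. With the groups counted once, that case gave 9.1 false calls and recovered 56.4% of the larger and 1.4% of the smaller changes.

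Genes called in NoBAL against Control and called in the opposite direction in hiHepD8 against NoBAL were counted as reverted. As both comparisons share the NoBAL libraries, 50 simulations of unchanged groups gave the correlation and covariance that sharing alone produces, and the count was repeated against EmptyBAL, which shares no library. The other settings were upper-quartile scaling, limma without the trend, no filter, a filter of 5 FPKM, pseudocounts of 0.1 and 5, a fit of only the 2 groups compared, a minimum log2 change of 1, the replicate number as a block, both hiHep days as 1 group, and leaving out each library in turn.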

Results

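Replicates differed in how closely they matched. Pearson correlation of log2(FPKM + 1) was 0.992 to 0.994 among the 3 Control libraries and 0.992 between the hiHepD8 libraries, but 0.956 between the NoBAL and 0.893 between the EmptyBAL libraries. Among genes with a mean of at least 10 FPKM, 0.15% to 0.3% differed 2-fold between Control libraries and 0.25% between the hiHepD8 libraries, against 11.47% for NoBAL (550 of 4795 genes) and 28.61% for EmptyBAL (1286 of 4495). The mean SD per gene was 0.18 in Control and 0.168 in hiHepD8, and 0.448 and 0.633 in NoBAL and EmptyBAL. Albumin transcripts made up 6.35% to 6.64% of the summed FPKM in Control, 0.93% and 1.46% in NoBAL, 0.3% and 0.92% in EmptyBAL, 1.19% in hiHepD4, and 2.3% and 2.37% in hiHepD8. Mitochondrially encoded protein genes held 14.5% to 15.9% in Control, 21.3% and 18.2% in NoBAL, 15.0% and 12.8% in EmptyBAL, 16.7% in hiHepD4, and 13.7% and 14.2% in hiHepD8. Each comparison also set day 0, 2, 3, 4 or 8 against another day, so time and treatment could not be separated.

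**Figure D1:**
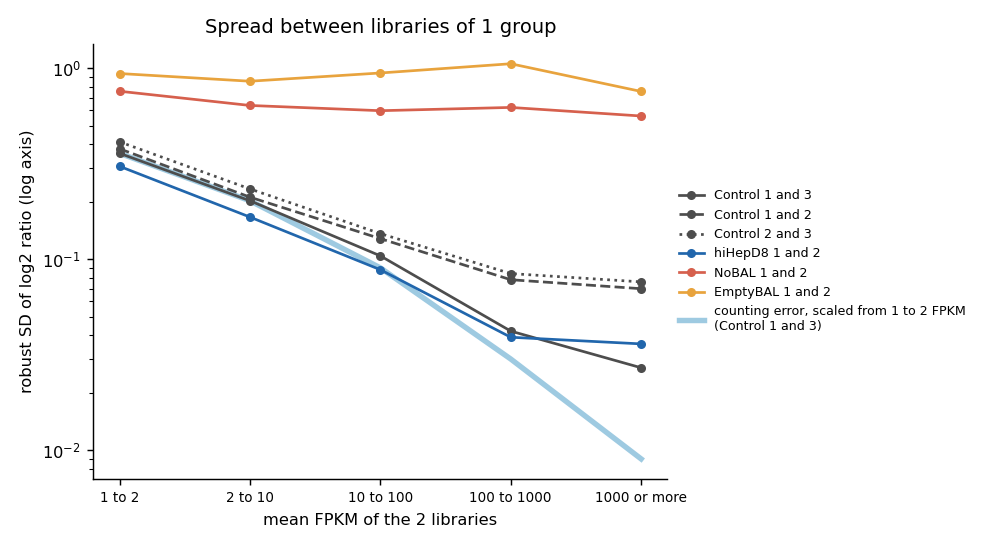
Robust SD of the log2 FPKM ratio between the libraries of a pair (vertical) in 5 bins of mean FPKM (horizontal), with the counting error scaled from the lowest bin as a line. At 1000 FPKM or more the spread was 0.027 for Control replicates 1 and 3 and 0.036 for the hiHepD8 pair, against 0.561 for NoBAL and 0.754 for EmptyBAL.

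NoBAL was compared with Control to find the genes that accompany liver failure after hepatectomy. Cell division genes rose from near absence, and genes for secreted proteins, drug metabolism and bile acid synthesis, the specialised work of hepatocytes, fell. Of these calls only that of the cell cycle held with an estimated correlation (adjusted p = 0.034, against 0.3, 0.38 and 0.071 for the others). With fry all of them held (adjusted p = 1.6e-06 for the cell cycle, and 0.00038, 0.0016 and 4.5e-06 for the others). UBE2C, a ubiquitin-conjugating enzyme of mitosis, was at 131 ± 46.0 FPKM (SD, n = 2) in NoBAL and 1.7 ± 0.554 (n = 3) in Control. The lipid droplet protein gene PLIN2 was at 738 ± 18.9 and 23.0 ± 1.28 FPKM. The cytochrome P450 gene CYP2A19, abundant in Control at 5540 ± 90.8 FPKM, was at 4.52 and 0.521 FPKM in the NoBAL libraries. ALB, chosen after the values were seen, was at 7521 ± 260 FPKM in NoBAL and 53929 ± 1472 in Control (log2 change -2.84 ± 0.45 SE, adjusted p = 0.0016, and 0.246 with groups counted once).

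The largest rises were those of S100A2 (log2 change 6.45 ± 0.31 SE), S100A12 (5.66 ± 0.98), UBE2C (5.58 ± 0.28), MAPK13 (5.18 ± 0.49) and the bile acid exporter subunit SLC51A (5.01 ± 1.06), with adjusted p = 7.7e-06 to 0.006. PLIN2 (4.94 ± 0.44), CCNB1 (4.87 ± 0.38), NPM3 (4.82 ± 0.23), CDC20 (4.78 ± 0.17) and TUBB (4.64 ± 0.16) followed, with adjusted p = 2.6e-06 to 0.0001. S100A12, a neutrophil gene, was at 170.536 and 20.4387 FPKM in the NoBAL libraries. The largest falls were those of CYP2A19 (-10.9 ± 1.42), CA3 (-8.57 ± 0.29), HRG (-7.31 ± 0.45), FOSB (-6.97 ± 0.18) and SERPINA6 (-6.82 ± 0.21), with adjusted p = 1.6e-06 to 0.0006. IGFALS (-5.94 ± 0.26), CYP1A2 (-5.90 ± 0.59), SARDH (-5.85 ± 0.31) and HAO1 (-5.81 ± 0.32) followed, with adjusted p = 5.5e-06 to 0.00018. PVALB belonged to this set but was listed at 0 in both NoBAL libraries, against 67.6591, 69.1125 and 61.3332 FPKM in Control, so no change is given. Of these 20 genes, 16 were also called with groups counted once. S100A12, SLC51A, CYP2A19 and CYP1A2 were not (adjusted p = 0.05 to 0.17). S100A2 (ENSSSCG00000006580) lies on chromosome 4 at 96073496 to 96076825, UBE2C on chromosome 17 at 48018403 to 48021542 and PLIN2 on chromosome 1 at 203683867 to 203709277. CYP2A19 lies on chromosome 6 at 49056579 to 49064111, CA3 on chromosome 4 at 51227485 to 51237861 and FOSB on chromosome 6 at 51836780 to 51844531.

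Among the fixed lists, cell cycle genes rose (31 of 33, 0 down, median log2 change 3.03, camera adjusted p = 2.2e-16). In this and the later comparisons, as many members were called when adjusted over the list alone, unless another number is given. Ribosome biogenesis genes such as NPM1, FBL and DKC1 rose (17 of 19, median 1.68, camera adjusted p = 9.8e-08), but with adjusted p = 0.3 with an estimated correlation. Mitochondrial respiration genes such as IDH3A and CYC1 rose (9 of 16, 10 over the list alone, median 0.86, camera adjusted p = 0.0045), with adjusted p = 0.46 with an estimated correlation.

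Secreted plasma protein genes such as TTR and APOH fell (16 of 20, 17 over the list alone, median -2.40, camera adjusted p = 1.5e-05). So did coagulation factors such as KNG1 (14 of 18, -2.43, camera adjusted p = 5.9e-06) and complement components such as C8B (13 of 16, -2.45, camera adjusted p = 1.8e-05). With an estimated correlation these 3 lists had adjusted p = 0.3, 0.38 and 0.38. Amino acid catabolism genes such as HAAO (14 of 20, 15 over the list alone, -2.59, camera adjusted p = 1.5e-05) and bile acid synthesis genes such as CYP7A1 (8 of 9, -2.25, camera adjusted p = 5.3e-05) fell, with adjusted p = 0.38 and 0.071 with an estimated correlation. Drug metabolism genes such as AOX1 (12 of 17, -2.68, camera adjusted p = 1.9e-05) and fatty acid oxidation genes such as ACAA2 (10 of 22, -1.03, camera adjusted p = 0.0007) fell, with adjusted p = 0.38 and 0.53 with an estimated correlation. Lipid and sterol synthesis genes (11 of 23 down and 2 up, -0.88, camera adjusted p = 0.0062) and gluconeogenesis genes (6 of 14, -1.30, camera adjusted p = 0.0062) followed, with adjusted p = 0.14 and 0.38 with an estimated correlation.

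Cytokine and chemokine genes such as CXCL2 and CCL4 fell (17 of 26 down and 1 up, median -1.53, camera adjusted p = 4.3e-05, and adjusted p = 0.38 with an estimated correlation). Immediate early genes (11 of 21 down and 1 up, -1.05, camera adjusted p = 0.0021) and T and NK cell markers such as CD2 (12 of 14, -1.41, camera adjusted p = 1.5e-05) also fell. With an estimated correlation they had adjusted p = 0.11 and 0.064. Class II antigen presentation genes fell for 5 of 6 (-0.77, camera adjusted p = 0.03, and adjusted p = 0.38 with an estimated correlation). The other 15 lists were not called (camera adjusted p = 0.065 to 1.0), urea cycle (5 of 12 down, median -1.27) and macrophage markers (7 of 19 down and 1 up, median -0.22) among them. For endothelial markers the median was 0.55 but the mean -0.13, and for cholangiocyte markers 0.18 and -0.10.

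limma called 6021 of 12180 genes in NoBAL against Control, 3068 up and 2953 down, of which 3606 changed at least 2-fold. There were 3360 called with pairs averaged and 419 with groups counted once (121 up, 298 down). Of the 419, 415 were among the 6021. Since simulated groups from a single animal gave 1849.2 false calls, the larger count rests on the libraries coming from separate animals. With 2 against 3 libraries, 20% of genes separate by chance alone.

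hiHepD8 was compared with NoBAL to find what differed in livers that had been treated with the cell-filled device and sampled on day 8. Amino acid breakdown genes were higher, and cell division and ribosome biogenesis genes were lower, of which the cell division call alone held with an estimated correlation (adjusted p = 0.037, against 0.33 for each of the others). SDS, which encodes a serine-degrading enzyme of gluconeogenesis, was at 1940 ± 25.3 FPKM (n = 2) in hiHepD8 and 18.1 ± 0.997 (n = 2) in NoBAL. TAT, the tyrosine aminotransferase gene, was at 3220 ± 24.0 and 88.0 ± 39.7 FPKM, and UBE2C was at 2.01 ± 0.597 FPKM in hiHepD8. ALB was at 12992 ± 15.8 FPKM in hiHepD8, a difference from NoBAL that was not called (log2 change 0.79 ± 0.50, adjusted p = 0.226).

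Largest among the higher genes were SDS (log2 change 6.67 ± 0.81), APOD (5.63 ± 0.42), CYP2A19 (5.50 ± 1.55), TAT (5.25 ± 0.66) and the glucose-6-phosphate transporter gene SLC37A4 (5.01 ± 0.44), with adjusted p = 8e-05 to 0.021. AASS (4.93 ± 0.46), APOF (4.89 ± 0.34), PTPRN (4.88 ± 0.16), LPIN1 (4.78 ± 0.14) and CHDH (4.76 ± 0.18) followed, with adjusted p = 6.2e-06 to 0.00017. Lower were PLIN2 (-7.04 ± 0.48), the organic anion transporter gene SLC22A7 (-6.33 ± 0.43), TK1 (-6.06 ± 0.34), PCLAF (-5.90 ± 0.35) and S100A12 (-5.77 ± 1.08), with adjusted p = 3e-05 to 0.0037. CDC20 (-5.55 ± 0.19), SLC25A47 (-5.53 ± 0.69), UBE2C (-5.42 ± 0.30), CCNB1 (-5.12 ± 0.42) and NME1 (-4.87 ± 0.25) followed, with adjusted p = 7.4e-06 to 0.00062. With groups counted once, 15 of these 20 were called, and SDS, CYP2A19, TAT, S100A12 and SLC25A47 were not (adjusted p = 0.06 to 0.22). SDS (ENSSSCG00000036865) lies on chromosome 14 at 38503922 to 38513908 and TAT (ENSSSCG00000002736) on chromosome 6 at 14571311 to 14583203.

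Among the lists, amino acid catabolism genes such as GNMT were higher (15 of 20, 0 lower, median log2 change 3.43, camera adjusted p = 1.6e-07, and adjusted p = 0.33 with an estimated correlation). Coagulation factors such as F11 (9 of 18, median 1.0, camera adjusted p = 0.023) and gluconeogenesis genes such as GYS2 (6 of 14 higher and 1 lower, 1.35, camera adjusted p = 0.028) were higher, with adjusted p = 0.76 and 0.59 with an estimated correlation. T and NK cell markers (7 of 14, 8 over the list alone, 0.64, camera adjusted p = 0.0042) and class II genes (5 of 6, 0.98, camera adjusted p = 0.028) were higher, with adjusted p = 0.22 and 0.47 with an estimated correlation. Cell cycle genes were lower (31 of 33, -3.36, camera adjusted p = 8.4e-16). Ribosome biogenesis genes such as NOP56 were lower (18 of 19, -1.75, camera adjusted p = 1.2e-08), with adjusted p = 0.33 with an estimated correlation. Mitochondrial respiration genes (9 of 16, -1.07, camera adjusted p = 0.0067) and immediate early genes (9 of 21 lower and 1 higher, 11 and 1 over the list alone, -1.14, camera adjusted p = 0.019) were lower, with adjusted p = 0.59 and 0.25 with an estimated correlation. The remaining 22 lists were not called (camera adjusted p = 0.051 to 0.92). Among these, secreted plasma proteins had 5 of 20 genes higher and 3 lower (3 and 3 over the list alone, median 0.54) and complement components 4 of 16 higher and 2 lower (3 and 2 over the list alone, 0.06). Bile acid transport had a median and a mean of -0.49 while its test pointed up (camera adjusted p = 0.92).

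limma called 5764 genes in hiHepD8 against NoBAL, 2740 higher and 3024 lower, 3695 of them at least 2-fold, 2016 with pairs averaged and 299 with groups counted once (188 higher, 111 lower). Upper-quartile scaling shifted the median change of all genes by 0.185 and moved the share of higher genes from 47.5% to 60.1% (3476 higher, 2306 lower), so the balance of higher and lower genes depended on scaling. Without either hiHepD8 library 3233 genes were called, and with 2 against 2 libraries 33.3% of genes separate by chance.

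hiHepD8 was compared with EmptyBAL to set the device with cells against the device without them. Genes for most hepatocyte functions were higher in hiHepD8, and genes of dividing cells and of immune cells were lower. The cell cycle call held with an estimated correlation (adjusted p = 0.031) and those of the hepatocyte and immune lists did not (adjusted p = 0.08 to 0.7). ASS1, a urea cycle enzyme gene, was at 6510 ± 212 FPKM (n = 2) in hiHepD8 and 147 ± 106 (n = 2) in EmptyBAL. GYS2, the liver glycogen synthase gene, was at 201 ± 1.1 and 3.16 ± 1.3 FPKM. The macrophage receptor gene MARCO was at 1.24 ± 0.333 FPKM in hiHepD8 and 118 ± 86.7 in EmptyBAL.

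The 5 largest differences upward were those of TAT (log2 change 7.38 ± 0.66), ASS1 (5.67 ± 0.54), SDS (5.66 ± 0.81), UPP2 (5.64 ± 0.56) and GYS2 (5.64 ± 0.24), with adjusted p = 2.4e-05 to 0.0015. SDS was at 12.1401 and 111.906 FPKM in the EmptyBAL libraries. Downward they were those of S100A12 (-7.24 ± 1.08), TK1 (-5.94 ± 0.34), S100A8 (-5.91 ± 1.18), CCL2 (-5.52 ± 0.59) and MARCO (-5.51 ± 0.45), with adjusted p = 4.1e-05 to 0.0062. In the EmptyBAL libraries S100A12 was at 442.508 and 62.9894 FPKM and S100A8 at 175.127 and 27.5747 FPKM. Of the 10 genes, GYS2 (chromosome 5, 51862952 to 51915153) and TK1 were also called with groups counted once, and the others had adjusted p = 0.057 to 0.16.

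Amino acid catabolism genes such as CTH were higher (19 of 20, median log2 change 4.34, camera adjusted p = 1.5e-10), as were coagulation factors such as PROC and F9 (18 of 18, 2.72, camera adjusted p = 1.5e-07). With an estimated correlation they had adjusted p = 0.19 and 0.36. Gluconeogenesis genes (12 of 14, with 1 lower over the list alone, 3.12, camera adjusted p = 5.6e-05) and urea cycle genes (6 of 12, 3.53, camera adjusted p = 0.02) were higher, with adjusted p = 0.28 and 0.67 with an estimated correlation. The urea cycle gap was larger for EmptyBAL replicate 1. Mean log2 differences of that list from Control were -4.038 and -1.556 in EmptyBAL, and -0.373 and -0.357 in hiHepD8. Secreted plasma proteins (11 of 20, 14 over the list alone, 1.75, camera adjusted p = 0.0015) and drug metabolism genes (11 of 17 higher and 1 lower, 2.40, camera adjusted p = 0.0015) were higher, with adjusted p = 0.37 and 0.48 with an estimated correlation. So were bile acid synthesis genes (7 of 9, 1.70, camera adjusted p = 0.0015) and bile acid transport genes (5 of 12, 6 over the list alone, 1.34, camera adjusted p = 0.035), with adjusted p = 0.1 and 0.6 with an estimated correlation. The difference in bile acid transport lay mainly in EmptyBAL replicate 1. Mean log2 differences of that list from Control were -2.888 and -1.008 in EmptyBAL, and -0.824 and -0.835 in hiHepD8. Hepatocyte transcription factors such as HNF4A were higher for 11 of 15 (1.79, camera adjusted p = 0.0014, and adjusted p = 0.44 with an estimated correlation).

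Cell cycle genes were lower (29 of 33, median -2.24, camera adjusted p = 3.7e-17). Macrophage markers (13 of 19, 14 over the list alone, -1.36, camera adjusted p = 2.4e-06) and T and NK cell markers (11 of 14, 12 over the list alone, -0.95, camera adjusted p = 5.3e-05) were lower, with adjusted p = 0.094 and 0.08 with an estimated correlation. Neutrophil markers (6 of 6, -2.70, camera adjusted p = 0.00021) and B cell markers (4 of 8, -0.77, camera adjusted p = 0.025) were lower, with adjusted p = 0.12 and 0.37 with an estimated correlation. Class II genes (3 of 6, 4 over the list alone, -0.87, camera adjusted p = 0.021) and ribosome biogenesis genes (10 of 19, -0.70, camera adjusted p = 7.7e-05) were lower, with adjusted p = 0.37 for both with an estimated correlation. Cytokines and chemokines (11 of 26 lower and 1 higher, -0.73, camera adjusted p = 0.00021) and immediate early genes (10 of 21 lower and 2 higher, -0.89, camera adjusted p = 0.0028) were lower, with adjusted p = 0.37 and 0.1 with an estimated correlation. Interferon response genes were lower by less (7 of 26 lower and 1 higher, -0.39, camera adjusted p = 0.033, and adjusted p = 0.7 with an estimated correlation). The other 12 lists were not called (camera adjusted p = 0.11 to 0.84), and among them endothelial markers had a median of 0.34 and a mean of -0.07.

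limma called 4895 genes in hiHepD8 against EmptyBAL, 2751 higher and 2144 lower, 3061 of them at least 2-fold, 1199 with pairs averaged and 34 with groups counted once (28 higher, 6 lower). A fit of only these 2 groups called 2353. Both groups held 2 libraries and the EmptyBAL libraries differed strongly from each other, so single genes such as S100A12 varied several-fold within the group. Without hiHepD8 replicate 1 or 2, 2263 and 2253 genes were called.

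Per the deposited description of the series, livers with the cell-filled device were compared to find genes that returned after a change in liver failure, so genes called in NoBAL against Control were followed into hiHepD8. Of the 6021 genes, 3685 (61.2%) were called in the opposite direction in hiHepD8 against NoBAL: 2126 of the 3068 that rose (69.3%) and 1559 of the 2953 that fell (52.8%). Cell cycle genes such as UBE2C and CCNB1 returned, and so did PLIN2, which fell below Control. The urea cycle gene OTC and the coagulation factor gene KNG1, which had fallen, were higher again in hiHepD8 than in NoBAL. Genes that rose in NoBAL had a median log2 difference from Control of 1.1 in NoBAL, 0.62 in EmptyBAL, 0.58 in hiHepD4 and 0.11 in hiHepD8. Genes that fell had -1.18, -1.14, -0.75 and -0.5. As the NoBAL values chose these genes, their NoBAL medians are overstated and other groups tend to lie nearer to Control. In hiHepD8, 1829 of the 2126 and 975 of the 1559 were not called against Control, while 533 genes that rose and 1262 that fell in NoBAL were still called in the same direction against Control. Not being called depended on the spread pooled over all groups and does not place a gene at the Control level. A fit of hiHepD8 and Control alone called 8384 genes, against 3923 here.

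**Figure D2:**
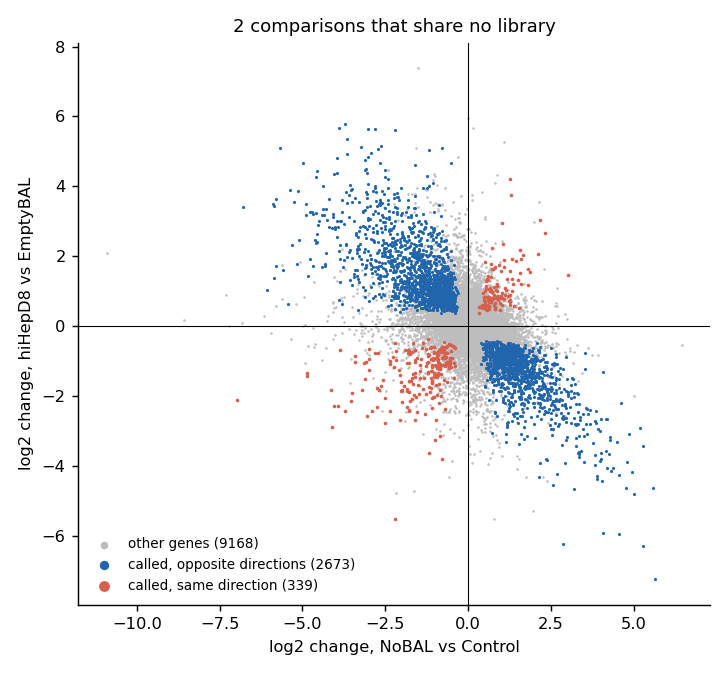
Log2 change of each of 12180 genes in NoBAL against Control (horizontal) and in hiHepD8 against EmptyBAL (vertical), which share no library; points are genes. Of the genes called in NoBAL against Control, 2673 were called in the opposite and 339 in the same direction.

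Both comparisons used the NoBAL libraries, so part of the excess may come from the shared libraries. Independent lists would have given 762 and 664 genes. The covariance of the changes was -0.934, against -0.1 in unchanged groups with each group's own spread (a difference of -0.834) and -0.054 with a pooled spread. The correlation was -0.66, against -0.89 and -0.547. Against EmptyBAL, with no shared library, 1185 genes that rose (38.6%, 540 for independent lists) and 1488 that fell (50.4%, 667) were called in the opposite direction, and 118 and 221 in the same direction (correlation -0.53, covariance -0.721). With EmptyBAL against Control and hiHepD8 against NoBAL, which also share none, the correlation was -0.27 and the covariance -0.437. Without hiHepD8 replicate 1 or 2, 2284 and 2275 genes were reverted. With groups counted once, 140 were reverted and 16 against EmptyBAL, while 340 of the 419 genes had the opposite sign there. Of the reverted genes, 1082 that rose in NoBAL and 392 that fell were already called in the opposite direction in EmptyBAL against NoBAL, leaving 1044 and 1167 that were not. All these comparisons share the NoBAL libraries, and no value for unchanged groups was computed for this split. The EmptyBAL against NoBAL calls also depended on scaling, with 1535 higher and 2611 lower as designed and 2212 and 1277 with upper-quartile scaling.

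EmptyBAL was compared with NoBAL to describe what accompanied the blood circuit without cells and 1 further day. Markers of macrophages and of T and NK cells were higher and genes of lipid synthesis, mitochondrial respiration and hepatocyte identity were lower. The calls of mitochondrial respiration and hepatocyte transcription factors were lost with an estimated correlation (adjusted p = 0.36 and 0.45), and the other 3 held (0.019 each). CD209, a receptor gene of macrophages and dendritic cells, was at 45.7 ± 11.6 FPKM (n = 2) in EmptyBAL and 0.767 ± 0.253 (n = 2) in NoBAL. CD163, a scavenger receptor gene of macrophages, was at 96.0 ± 16.8 and 10.7 ± 0.493 FPKM (log2 change 3.04 ± 0.18, adjusted p = 0.00036). The plasma protein gene ITIH4 was at 201 ± 33.5 FPKM in EmptyBAL and 5630 ± 3850 in NoBAL.

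The 5 genes with the largest differences upward were CD209 (log2 change 4.71 ± 0.29), GNLY (3.93 ± 0.70), MZB1 (3.69 ± 0.42), CLEC4G (3.51 ± 0.52) and LY86 (3.41 ± 0.32), with adjusted p = 0.00036 to 0.0076. Downward they were MFSD2A (-4.96 ± 0.92), ITIH4 (-4.62 ± 0.46), GSTA1 (-4.42 ± 0.80), APOA4 (-4.41 ± 1.41) and CYP2D6 (-4.22 ± 0.41), with adjusted p = 0.0015 to 0.046. APOA4 was at 7.92609 and 283.925 FPKM in the EmptyBAL and at 480.821 and 2390.85 in the NoBAL libraries. CD209 (ENSSSCG00000013579) lies on chromosome 2 at 71394414 to 71397711. With groups counted once, limma called 0 of the 10 (adjusted p = 0.1 to 0.23).

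Macrophage markers were higher for 18 of 19 genes (median log2 change 2.61, camera adjusted p = 2.6e-12) and T and NK cell markers such as GNLY for 13 of 14 (1.72, camera adjusted p = 2e-11). Class II genes (6 of 6, 1.82, camera adjusted p = 1.2e-05) and neutrophil markers (4 of 6, 1.58, camera adjusted p = 0.0019) were higher, with adjusted p = 0.22 for both with an estimated correlation. Cytokines and chemokines (9 of 26, 10 and 2 lower over the list alone, 0.88, camera adjusted p = 2.8e-05) and B cell markers (4 of 8, 0.79, camera adjusted p = 0.0053) were higher, with adjusted p = 0.36 for both with an estimated correlation. Matrix and stellate cell genes (9 of 33 higher and 1 lower, 8 and 1 over the list alone, 0.66, camera adjusted p = 0.00019) and endothelial markers (4 of 17, 0.44, camera adjusted p = 0.0055) were higher, with adjusted p = 0.36 and 0.46 with an estimated correlation. Cholangiocyte markers were higher for 6 of 10 and lower for 1 (7 and 1 over the list alone, 1.08, camera adjusted p = 0.00065, and adjusted p = 0.28 with an estimated correlation).

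Beside these higher marker values of other cell types, lipid and sterol synthesis genes were lower (17 of 23, 19 over the list alone, median -1.37, camera adjusted p = 6.1e-07). Fatty acid oxidation genes (15 of 22, 16 over the list alone, -1.23, camera adjusted p = 6e-05) and coagulation factors such as FGG (12 of 18, 13 over the list alone, -1.75, camera adjusted p = 0.00038) were lower, with adjusted p = 0.46 for both with an estimated correlation. Secreted plasma proteins such as TF (8 of 20, 9 over the list alone, -1.51, camera adjusted p = 0.013) and gluconeogenesis genes (8 of 14, 9 over the list alone, -1.99, camera adjusted p = 0.0027) were lower, with adjusted p = 0.46 and 0.38 with an estimated correlation. Hepatocyte transcription factors (11 of 15, 12 over the list alone, -1.49, camera adjusted p = 0.0003) and bile acid transport genes (5 of 12, -1.51, camera adjusted p = 0.03) were lower, with adjusted p = 0.45 and 0.56 with an estimated correlation. Both gaps were larger for EmptyBAL replicate 1. Mean log2 differences of the transcription factors from Control were -3.076 and -1.572 in EmptyBAL, and -0.707 and -0.748 in NoBAL. Those of bile acid transport were -2.888 and -1.008, and -0.424 and -0.251. Mitochondrial respiration genes (11 of 16, 13 over the list alone, -1.23, camera adjusted p = 0.00013) and ribosome biogenesis genes (16 of 19, 18 over the list alone, -1.01, camera adjusted p = 2.5e-06) were lower, with adjusted p = 0.36 for both with an estimated correlation. So were acute phase genes (4 of 13, -1.74, camera adjusted p = 0.028) and cell cycle genes (15 of 33, 16 over the list alone, -0.65, camera adjusted p = 0.00081), with adjusted p = 0.63 and 0.22 with an estimated correlation. The remaining 11 lists were not called (camera adjusted p = 0.054 to 0.96). Immediate early genes had a median of -0.44 and a mean of -0.28 and oxidative stress genes -0.17 and -0.18, while the tests of both pointed up.

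limma called 4146 genes in EmptyBAL against NoBAL, 1535 higher and 2611 lower, 2365 of them at least 2-fold and 561 with pairs averaged. With groups counted once, limma called 0 genes, and 2657 had an unadjusted p under 0.05. In a fit of only these 2 groups it also called 0, with 2659 at an unadjusted p under 0.05. Upper-quartile scaling shifted the median change of all genes by 0.198 and moved the share of higher genes from 37% to 63.4% (2212 higher, 1277 lower). Without EmptyBAL replicate 2, 6598 genes were called.

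EmptyBAL was also compared with Control to see how far livers on the empty device stood from normal liver. Nearly all hepatocyte functions were lower, and genes of cell division, of macrophages and of neutrophils were higher. The calls of the cell cycle and of lipid synthesis held with an estimated correlation (adjusted p = 0.023 each), but those of macrophages (0.1), neutrophils (0.16) and the other hepatocyte lists (0.051 to 0.45) did not. S100A6 was at 332 ± 160 FPKM (n = 2) in EmptyBAL and 3.63 ± 1.29 (n = 3) in Control. TIMP1, a metalloproteinase inhibitor gene, was at 2706.26 and 351.367 FPKM in the EmptyBAL libraries and 23.6 ± 0.0686 in Control, and ALB was at 1498.12 and 4057.45 FPKM in EmptyBAL.

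Largest upward were S100A12 (log2 change 7.13 ± 0.98), S100A6 (6.12 ± 0.50) and TIMP1 (5.31 ± 0.81, chromosome X, 42103251 to 42106289), with adjusted p = 6.8e-05 to 0.0012. The small RNA gene U3 (adjusted p = 0.011, 1135.59 and 11.7255 FPKM) and S100A8 (adjusted p = 0.0022) were listed at 0 in all Control libraries. The U3 symbol stood for 22 genes of the table, so its identity is uncertain. Largest downward were CA3 (-8.06 ± 0.29), CYP2A19 (-7.50 ± 1.42), SERPINA6 (-6.67 ± 0.21), CYP2D6 (-6.24 ± 0.37) and HSD17B6 (-6.12 ± 0.21), with adjusted p = 2.1e-06 to 0.0032. CYP2A19 was at 226.183 and 3.14417 FPKM in the EmptyBAL libraries. With groups counted once 5 of the 10 were called, and S100A12, U3, S100A8, TIMP1 and CYP2A19 were not (adjusted p = 0.065 to 0.18).

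Cell cycle genes were higher (30 of 33, 31 over the list alone, median log2 change 2.26, camera adjusted p = 2.4e-14). Macrophage markers (13 of 19, 2.02, camera adjusted p = 3e-05) and neutrophil markers (6 of 6, 2.82, camera adjusted p = 0.00089) were higher, with adjusted p = 0.1 and 0.16 with an estimated correlation. Matrix genes such as TIMP1 were higher for 19 of 33 and lower for 3 (20 and 3 over the list alone, 1.25, camera adjusted p = 0.00053, and adjusted p = 0.33 with an estimated correlation). Lipid and sterol synthesis genes were lower (20 of 23, -2.16, camera adjusted p = 4.7e-08). Coagulation factors (18 of 18, -4.02, camera adjusted p = 1.9e-08) and fatty acid oxidation genes (22 of 22, -2.50, camera adjusted p = 5.9e-08) were lower, with adjusted p = 0.3 and 0.32 with an estimated correlation. Secreted plasma proteins (19 of 20, -4.34, camera adjusted p = 1.1e-07) and amino acid catabolism genes (18 of 20, 19 over the list alone, -3.69, camera adjusted p = 3.4e-07) were lower, with adjusted p = 0.16 and 0.29 with an estimated correlation. Drug metabolism genes (16 of 17, -3.89, camera adjusted p = 1.9e-06) and bile acid synthesis genes (9 of 9, -2.80, camera adjusted p = 1.3e-05) were lower, with adjusted p = 0.32 and 0.051 with an estimated correlation.

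Gluconeogenesis genes (14 of 14, median -3.30) and complement components (15 of 16 lower and 1 higher, -3.86) were lower too, with camera adjusted p = 2.1e-05 and 3.1e-05 and adjusted p = 0.26 and 0.32 with an estimated correlation. Hepatocyte transcription factors (12 of 15, -2.33), urea cycle genes (8 of 12, -2.76), bile acid transport genes (9 of 12, -2.26), acute phase genes (10 of 13 lower and 1 higher, -2.53) and immediate early genes (14 of 21 lower and 2 higher, 15 and 2 over the list alone, -1.95) had camera adjusted p = 0.00014 to 0.0066. With an estimated correlation these had adjusted p = 0.1 to 0.45. Ribosome biogenesis (11 of 19 higher and 1 lower, 0.54), class II (5 of 6, 0.87), glycolysis (11 of 20 higher and 2 lower, 0.57), endothelial (7 of 17 higher and 2 lower, 0.56) and cholangiocyte genes (4 of 10 higher and 2 lower, 0.58) were higher, with camera adjusted p = 0.0024 to 0.048. With an estimated correlation these had adjusted p = 0.33 to 0.52. The other 8 lists were not called (camera adjusted p = 0.084 to 0.69), with a median of -0.09 and a mean of 0.05 for the interferon response.

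limma called 6540 genes in EmptyBAL against Control, 2967 higher and 3573 lower, 4050 of them at least 2-fold, 3922 with pairs averaged and 692 with groups counted once (161 higher, 531 lower). Upper-quartile scaling shifted the median change of all genes by 0.177 and moved the share of higher genes from 45.4% to 57% (3853 higher, 2902 lower). Of the genes called in NoBAL against Control, 1612 that rose and 2203 that fell were called in the same direction here. The changes correlated at 0.74 with a covariance of 1.234. In unchanged groups that share Control these were 0.071 and 0.011 with each group's own spread, and 0.403 and 0.036 with a pooled spread. The simulation drew the Control libraries independently. If they came from a single animal, sharing Control alone could give more than these values.

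hiHepD8 was compared with Control to see what differed from normal liver on day 8. The cell cycle list was not called, while immediate early, lipid synthesis, fatty acid oxidation and complement genes were lower and matrix genes were higher. The immediate early and lipid synthesis calls held with an estimated correlation (adjusted p = 0.045 each), but not those of fatty acid oxidation (0.43), complement (0.36) and matrix genes (0.56). Immediate early genes also lay below Control in NoBAL, EmptyBAL and hiHepD4 (mean log2 differences of the list -1.228 to -1.801). Whether the gap lay in high Control values or in low values elsewhere was not tested. FOSB was at 0.484 FPKM in hiHepD8 (n = 2) and 337 ± 0.91 in Control (n = 3). MMP2, a matrix metalloproteinase gene, was at 226 ± 3.71 and 8.89 ± 1.09 FPKM, and MBL2, a lectin gene of the complement system, at 0.603 and 174 ± 10.5 FPKM.

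Largest upward were SDS (log2 change 6.84 ± 0.74), APOD (6.04 ± 0.39, chromosome 13, 132514546 to 132562594), AFMID (4.98 ± 0.37), NRIP3 (4.74 ± 0.38) and MMP2 (4.53 ± 0.55), with adjusted p = 5e-05 to 0.0008. Largest downward were CA3 (-7.90 ± 0.29), FOSB (-7.83 ± 0.18), MBL2 (-6.78 ± 0.64), FADS2 (-6.71 ± 0.17) and ATF3 (-6.67 ± 0.21), with adjusted p = 1.2e-06 to 0.00025. CA3, FOSB, FADS2 and ATF3 were called with groups counted once and the other 6 were not (adjusted p = 0.094 to 0.21).

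Of 33 cell cycle genes, 1 was higher and 4 were lower (0 and 3 over the list alone, median log2 change -0.14, camera adjusted p = 0.33). Immediate early genes (14 of 21, -2.23, camera adjusted p = 2e-07) and lipid and sterol synthesis genes (16 of 23 lower and 2 higher, 17 and 3 over the list alone, -1.87, camera adjusted p = 5.9e-06) were lower. Fatty acid oxidation genes (17 of 22, 21 over the list alone, -1.70, camera adjusted p = 2.7e-08) and complement components such as MBL2 (13 of 16, 16 over the list alone, -2.58, camera adjusted p = 9.2e-07) were lower, with adjusted p = 0.43 and 0.36 with an estimated correlation. Cytokines and chemokines (19 of 26 lower and 2 higher, 20 and 2 over the list alone, -1.51, camera adjusted p = 6.4e-07) and secreted plasma proteins (11 of 20, -1.89, camera adjusted p = 1e-05) were lower, with adjusted p = 0.37 and 0.36 with an estimated correlation. Coagulation factors (9 of 18, 12 over the list alone, -1.24, camera adjusted p = 0.00013) and bile acid synthesis genes (7 of 9, -1.74, camera adjusted p = 0.0013) were lower, with adjusted p = 0.57 and 0.14 with an estimated correlation.

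Drug metabolism genes (7 of 17, median -1.38, camera adjusted p = 0.0032) and T and NK cell markers (9 of 14, 11 and 2 higher over the list alone, -0.70, camera adjusted p = 0.003) were lower, with adjusted p = 0.67 and 0.14 with an estimated correlation. Unfolded protein response genes (10 of 20 lower and 1 higher, 11 and 1 over the list alone, -0.94, camera adjusted p = 0.0012) and acute phase genes (6 of 13 lower and 1 higher, -1.0, camera adjusted p = 0.018) were lower, with adjusted p = 0.67 for both with an estimated correlation. Matrix genes such as MMP2 (16 of 33 higher and 3 lower, 0.74, camera adjusted p = 0.0012) and cholangiocyte markers (6 of 10 higher and 1 lower, 7 and 1 over the list alone, 0.78, camera adjusted p = 0.011) were higher, with adjusted p = 0.56 and 0.43 with an estimated correlation. The other 16 lists beside the cell cycle were not called (camera adjusted p = 0.051 to 0.92). Gluconeogenesis had a median of -0.20 and a mean of -0.16 while its test pointed up, and macrophage markers had -0.25 and 0.14.

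limma called 3923 genes in hiHepD8 against Control, 1839 higher and 2084 lower, 2211 of them at least 2-fold, 763 with pairs averaged and 17 with groups counted once (3 higher, 14 lower). A fit of only these 2 groups called 8384. Upper-quartile scaling shifted the median change of all genes by 0.165 and moved the share of higher genes from 46.9% to 62% (2580 higher, 1580 lower). The count was 1524 without hiHepD8 replicate 1, 1592 without hiHepD8 replicate 2, 2607 without Control replicate 1 and 2606 without Control replicate 3. Across the 6 comparisons, the list calls that held with an estimated correlation were the cell cycle in NoBAL against Control (adjusted p = 0.034), hiHepD8 against NoBAL (0.037), hiHepD8 against EmptyBAL (0.031) and EmptyBAL against Control (0.023), lipid and sterol synthesis in EmptyBAL against NoBAL (0.019), EmptyBAL against Control (0.023) and hiHepD8 against Control (0.045), macrophage and T and NK cell markers in EmptyBAL against NoBAL (0.019 each), and immediate early genes in hiHepD8 against Control (0.045). With fry, the lists called by camera also had adjusted p under 0.05, with few exceptions. Against Control these were endothelial markers in EmptyBAL (fry adjusted p = 0.1) and acute phase genes in hiHepD8 (0.055). Against EmptyBAL it was the interferon response in hiHepD8 (0.18).

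**Figure D3:**
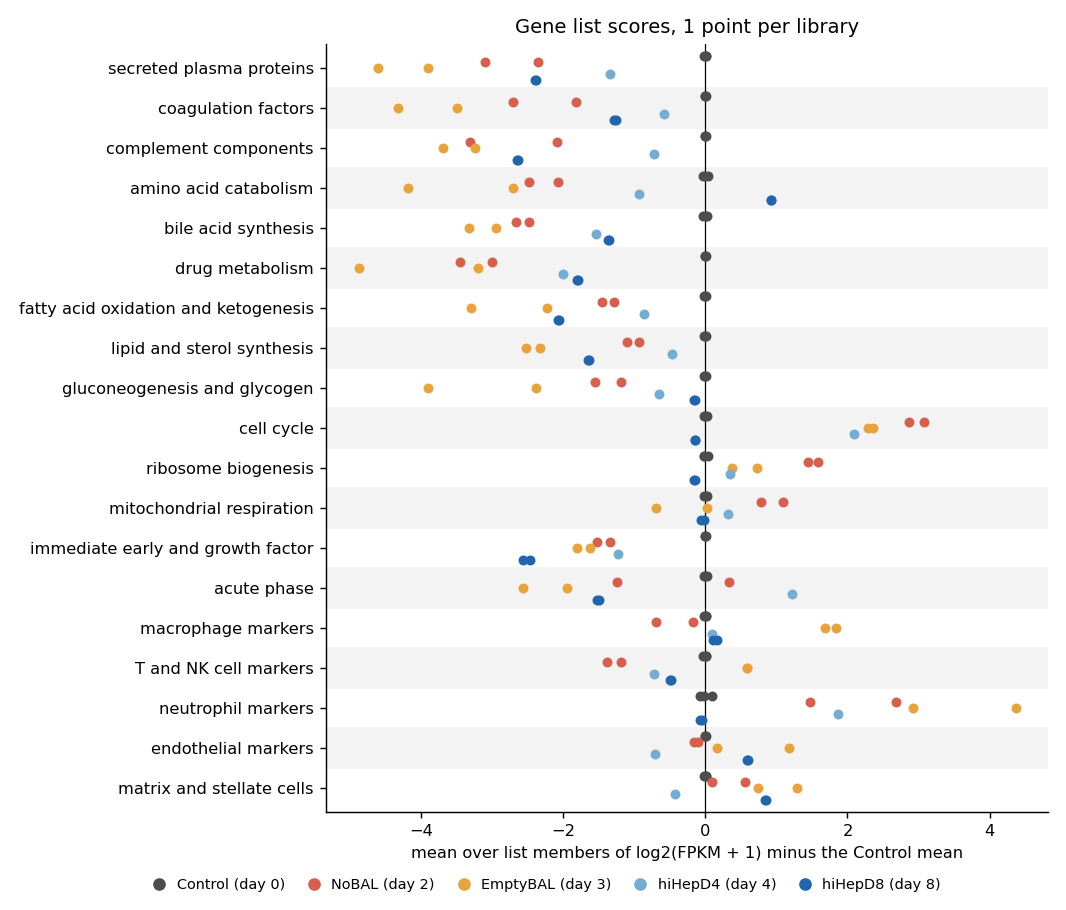
Mean over the members of 19 lists of log2(FPKM + 1) minus the Control mean, 1 point per library, by group. Cell cycle scores were 2.861 and 3.077 in NoBAL, 2.291 and 2.353 in EmptyBAL, 2.087 in hiHepD4, and -0.14 and -0.148 in hiHepD8.

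hiHepD4 showed where a liver stood on day 4 of the cell-filled device. As a single library it was described without a test. FPKM of the acute phase genes ITIH4, CP and LBP were 15800, 698 and 334 in hiHepD4, above each of the other 9 libraries, and so were those of the fibrinogen genes FGG and FGB, 16800 and 17100. Against NoBAL, coagulation factors were higher for 18 of 18 genes (median log2 difference 1.68), complement for 16 of 16 (1.77), secreted plasma proteins for 19 of 20 (1.29) and acute phase genes for 12 of 13 (1.85). Against Control, coagulation factors (4 higher and 14 lower, -0.69), complement (-0.34) and secreted plasma proteins (3 higher and 17 lower, -1.06) were mostly lower. Acute phase genes were above Control for 10 of 13 (0.77, percentile 99.9 among random lists), cell cycle genes for 33 of 33 (2.17), the unfolded protein response for 15 of 20 (0.89), oxidative stress genes such as HMOX1 and SOD2 for 9 of 12 (0.99) and glycolysis for 17 of 20 (0.8), each of the last 4 at percentile 100. Cell cycle genes were below NoBAL for 30 of 33 genes (-0.8), and class II genes were below Control for 6 of 6 (-1.19). Of the genes changed in NoBAL against Control, 1505 of 3068 that rose and 1182 of 2953 that fell were nearer to Control than to NoBAL in hiHepD4, against 2404 and 1615 in hiHepD8. As the NoBAL values chose these genes, some of this would arise without any return. No value for unchanged groups was computed for these counts.

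**Figure D4:**
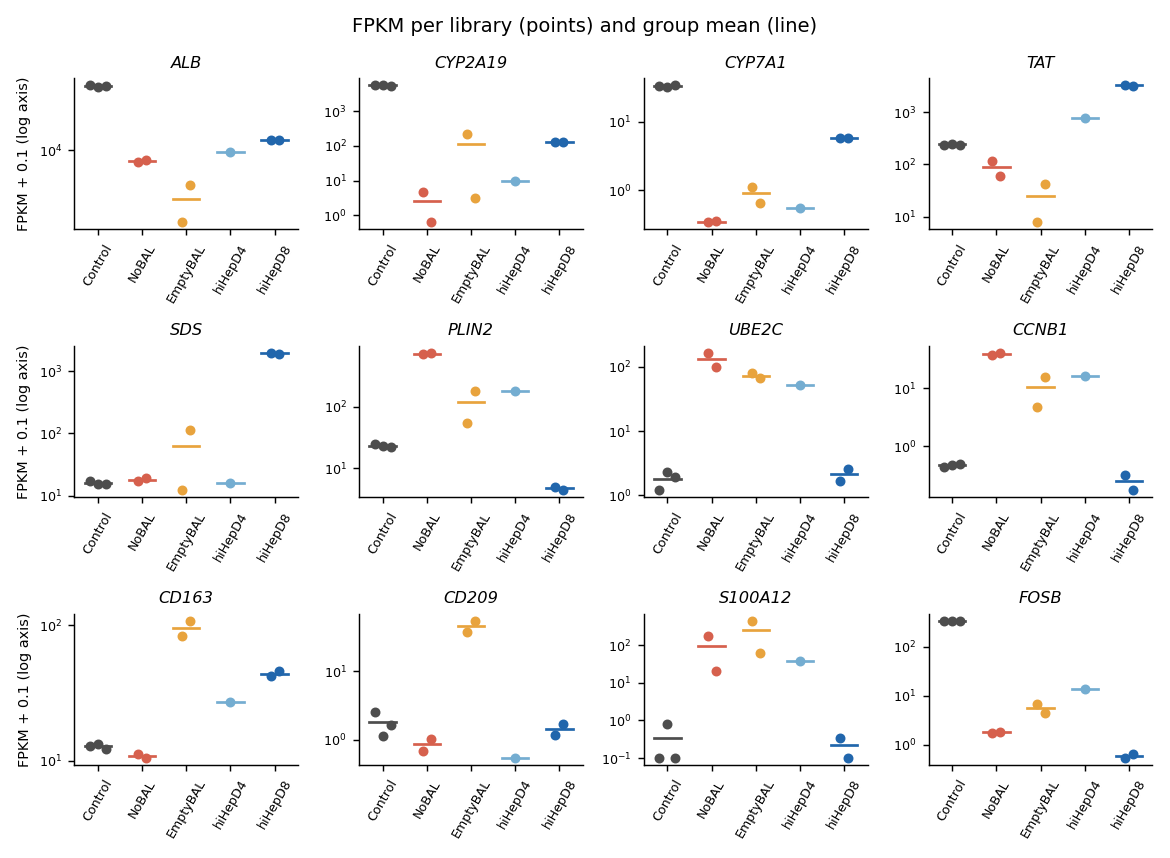
FPKM + 0.1 on a log axis for 12 genes in the 5 groups; points are libraries and lines are group means. UBE2C was at 131 FPKM in NoBAL and 2.01 in hiHepD8, and TAT at 88.0 and 3220 FPKM.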

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

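The tests of explanations in this part, and the search of hiHepD4 for genes found there alone, were chosen after the results were seen. Because the EmptyBAL and NoBAL effects were measured against the same Control libraries, the comparison of EmptyBAL with NoBAL is also the test of whether these effects differ, and 3 lists differed there with an estimated correlation (adjusted p = 0.019 each). Lipid and sterol synthesis differed by a median log2 change of -1.37, macrophage markers by 2.61 and T and NK cell markers by 1.72. For macrophage markers, the EmptyBAL effect was higher for 18 of 19 genes.

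Macrophage and T and NK cell markers were higher in EmptyBAL than in NoBAL, and 3 explanations were set against each other. A single deviating EmptyBAL library was argued against, as the macrophage median was 2.29 with either EmptyBAL library left out. The T and NK cell median was then 1.77 and 1.9. Mean log2 differences of the macrophage list from Control were 1.842 and 1.678 in the EmptyBAL libraries, and -0.699 and -0.179 in NoBAL. For T and NK cell markers they were 0.588 and 0.585 in EmptyBAL, and -1.189 and -1.384 in NoBAL. A lower share of hepatocytes that raised every other cell type alike was also argued against, since the macrophage median of 2.61 over 19 genes exceeded that of 50 endothelial and stellate genes, 0.64, by 1.96 (permutation p = 1e-05 in 100000 resamples, the smallest they can give). Against Control, T and NK cell markers were lower in NoBAL (12 of 14, median -1.41, camera adjusted p = 1.5e-05, and 0.064 with an estimated correlation). In EmptyBAL they were not called (5 higher and 2 lower, 0.31, camera adjusted p = 0.16), so their gap lay mainly in low NoBAL values. Macrophage markers were higher in EmptyBAL than in Control (13 of 19, 2.02, camera adjusted p = 3e-05, and 0.1 with an estimated correlation). NoBAL and EmptyBAL shared 0 days, so the device and the day of sampling cannot be told apart. Whether cell numbers or transcripts per cell differed was not tested.

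hiHepD4, which entered tests only where both hiHep days were pooled, held 3 genes at 10 FPKM or more that were at least 20 times higher than in any of the other 9 libraries. The fetal liver protein gene AFP was at 83.9 FPKM, against 0 to 0.77 elsewhere. Genes without a symbol, ENSSSCG00000018178 at 859 FPKM and ENSSSCG00000033084 at 30.2 FPKM, were listed at 0 in the other 9 libraries. With a single hiHepD4 library, these values were not tested.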

How the results depend on the processing

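Averaged pairs and groups counted once were added after the data had been seen; the other alternatives were planned. In the order NoBAL against Control, hiHepD8 against NoBAL, hiHepD8 against EmptyBAL, EmptyBAL against NoBAL, EmptyBAL against Control, hiHepD8 against Control and reverted genes, pairs averaged gave 3360, 2016, 1199, 561, 3922, 763 and 1268 genes, and groups counted once 419, 299, 34, 0, 692, 17 and 140, with fewer libraries and degrees of freedom. A minimum log2 change of 1 gave 3606, 3695, 3061, 2365, 4050, 2211 and 1994. With both hiHep days pooled, the comparisons of hiHepD8 with NoBAL, EmptyBAL and Control gave 2747, 3125 and 1754 genes and 2043 were reverted. A fit of only the 2 groups gave 2353 for hiHepD8 against EmptyBAL, 0 for EmptyBAL against NoBAL (limma, 2659 at an unadjusted p under 0.05) and 8384 for hiHepD8 against Control, with each pair's own spread. Replicate number as a block gave 2502 for EmptyBAL against NoBAL and 2341 for hiHepD8 against Control. With 2 pairs (correlation of same-numbered NoBAL and EmptyBAL libraries 0.137), it cannot be told whether the numbers pair the libraries. Leaving out 1 library gave 4599 to 5521, 3233 to 5383, 2253 to 6711, 3087 to 6598, 5154 to 7562, 1524 to 2619 and 2275 to 3503 genes, a lone library being assumed to vary like the other groups. The count moved over 1.5 times without hiHepD8 replicate 1 (3233, 2263 and 1524 for hiHepD8 against NoBAL, EmptyBAL and Control, and 2284 reverted) or 2 (3233, 2253, 1592 and 2275), without EmptyBAL replicate 2 (6598 for EmptyBAL against NoBAL), and without Control replicate 1 or 3 (2607 and 2606 for hiHepD8 against Control); the cause was not tested. A filter of 5 FPKM, no filter, no trend, pseudocounts of 0.1 and 5 and upper-quartile scaling left all 7 counts within 1.5 times. Among results called in either setting, directions reversed only with both hiHep days pooled. These were OIT3 against EmptyBAL (-0.12), and against Control TK1 (0.07), CDC20 (0.68), CCNB2 (0.42) and the cell cycle list (0.58, camera adjusted p = 0.0099). The reversals against Control came with adding hiHepD4, where 33 of 33 cell cycle genes were above Control. That of OIT3 was not examined. Of 753 named gene results, 620 lost their call with groups counted once, 321 with pairs averaged, 176 with 2 groups only, 95 without a filter, 87 with the block, 31 with upper-quartile scaling, 29 and 19 with pseudocounts of 5 and 0.1, and 5 without the trend. Of 186 list results, 91 lost theirs with an estimated correlation. Groups counted once ended 2 and added 6, upper-quartile scaling ended 2 and added 8, no filter ended 5 and added 21, and a filter of 5 FPKM ended 8 and added 7. With both hiHep days pooled, 8 list calls ended and 10 were added, and 142 named gene results lost their call.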

Other observations

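The tests of explanations in this part were chosen after the results were seen. Single bile acid transport genes changed in liver failure, while the list of 12 was not called (2 up, 4 down, camera adjusted p = 0.33). SLC51A was at 34.0 ± 4.93 FPKM in NoBAL (n = 2) and 0.0843 ± 0.0422 in Control (n = 3), and its partner SLC51B at 19.2 ± 1.07 and 0.532 ± 0.325 FPKM (log2 change 3.74 ± 0.62, adjusted p = 0.0019), though neither was called with groups counted once (adjusted p = 0.17 and 0.12). The uptake transporter gene SLC10A1 was at 3.25 ± 0.35 FPKM in NoBAL and 68.3 ± 0.436 in Control (-4.03 ± 0.28, adjusted p = 3.5e-05), and the bile acid synthesis gene CYP7A1 at 0.249 ± 0.014 and 33.4 ± 0.946 FPKM (-4.78 ± 0.15, adjusted p = 2.2e-06). In hiHepD8, SLC51A was at 0.328 and SLC51B at 0.44 FPKM, while SLC10A1 was at 28.8 FPKM (2.81 ± 0.30 above NoBAL, adjusted p = 0.00032) and CYP7A1 at 5.77 FPKM (2.44 ± 0.16 above NoBAL, adjusted p = 5e-05).

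The immediate early genes FOS and ATF3 were highest in Control: FOS was at 447 ± 10.3 FPKM there, 26.6 ± 14.0 in NoBAL, 46.3 ± 18.8 in EmptyBAL, 66.5 in hiHepD4 and 5.08 ± 0.0238 in hiHepD8, and ATF3 at 200, 12.5 and 0.975 FPKM in Control, NoBAL and hiHepD8. In hiHepD8 AQP1, a member of the cholangiocyte and progenitor list, was higher than in NoBAL and in EmptyBAL (51.2 ± 0.947 FPKM, against 2.84 ± 1.96 in NoBAL and 11.5 ± 6.67 in EmptyBAL). The lipid synthesis genes FASN (278 ± 7.11 against 24.6 ± 5.65 FPKM; log2 change 3.46 ± 0.32, adjusted p = 0.00027) and SREBF1 (97.8 ± 1.56 against 11.7 ± 1.67; 2.96 ± 0.17, adjusted p = 4.1e-05) were higher than in EmptyBAL, where the list of lipid and sterol synthesis was not called (8 of 23 higher and 2 lower, camera adjusted p = 0.11). The cholangiocyte and progenitor list as a whole was not called in either comparison. Against NoBAL 5 of its 10 genes were higher and 1 was lower (camera adjusted p = 0.07), and against EmptyBAL 2 were higher and 3 lower (0.72).

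The libraries within Control and within hiHepD8 were nearly identical. At most 0.3% of genes with a mean of at least 10 FPKM differed 2-fold between them, a value that sequencing the same RNA more than once would give and that the NoBAL and EmptyBAL pairs, at 11.47% and 28.61%, exceeded. At 1000 FPKM or more, Control pairs still spread 3.1 to 7.6 times and the hiHepD8 pair 4.6 times the counting error, so some handling may have been separate. The labels name an animal for 0 of the 10 libraries, so separate animals that vary little and repeated sequencing cannot be told apart.

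Cell cycle genes were raised in NoBAL, EmptyBAL and hiHepD4 and near the Control level in hiHepD8 (median log2 change -0.14 against Control). A chance rise of the shared NoBAL libraries was argued against by hiHepD8 against EmptyBAL, which does not use them (median log2 change -2.24, camera adjusted p = 3.7e-17). Upper-quartile scaling shifted the median change of all genes by 0.185 in hiHepD8 against NoBAL, too little to undo the cell cycle median of -3.36. Under it that median was -3.22 (camera adjusted p = 1.8e-18). As this setting was bound to leave the fall, it was no separate test of scaling. As 0 days held libraries both with and without the cell-filled device, an end of regeneration by day 8 and an effect of the cells cannot be told apart, and either may underlie the fall.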
